A study of Saccharomyces cerevisiae BY4741 with 4 samples.

How the data were processed

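The data come from log-phase cultures of Saccharomyces cerevisiae BY4741 grown in rich glucose medium to an optical density of 0.6, per the labels' protocols. Schizosaccharomyces pombe cells were added at 25% of the volume as a spike-in, nuclei were treated with micrococcal nuclease, and nucleosomes were precipitated with an antibody against H3K4me3, per the labels' protocols. The series has 4 libraries with 1 per label: a wild-type input, a wild-type H3K4me3 library, an spp1 H3K4me3 library and an spp1 library whose title names no assay. The deposited gene table holds 1 level per gene for each of the H3K4me3 libraries, and the values of the other libraries were not analysed here.

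The authors deposited these levels as a normalised H3K4me3 signal per gene, per the file headers. The series text ties comparability of the strains to the spike-in. How reads became levels, which part of each gene was averaged, and whether the input was divided out are not given in the sources used here. Bowtie2, SAMtools and bedtools were used with the genome builds sacCer3 for budding yeast and ASM294v2 for fission yeast, per the submitters' processing notes. Their versions are not given in the sources used here. The values were taken as linear: none is below 0 and none moves in whole-read steps, so read counts could not be recovered. Read depth per library is therefore unknown, and no counting interval is given.

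The table had 5219 genes after 3 lines had been emptied before this work. Systematic names were matched to the RefSeq annotation of the same budding yeast assembly, with 5116 matches and 103 names left without an annotated gene. The matches included 5113 of 6021 annotated protein-coding genes. A level in both libraries was present for 5038 genes, since the 180 genes of chromosome IX and 1 other gene, COS12, had none in the deletion strain. Both levels were identical to those of another gene for 103 genes in 51 groups, so such genes are not separate measurements. A level missing in the deletion strain counted as identical here, and whether such genes are neighbours was not checked. Coordinates are 1-based, from that annotation. Chromosome ends were taken as the outermost annotated gene ends, since no genome sequence was used here.

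For each gene the log2 ratio of the deletion strain to wild type was computed from the levels as deposited, with no pseudocount and no filter on low levels. Medians over genes carry distribution-free 95% intervals from binomial order statistics. With 1 library per strain, these intervals describe genes and not replicates, and no test between strains was made. Gene lists were summarised by the median log2 ratio and by its percentile among 10000 random lists of the same size, drawn with a fixed seed from 20 bins of the mean log2 level of both libraries. That mean includes the deletion strain's level, so such matching can take away part of a difference it is meant to show. It can also enlarge or create a difference. Lists matched on wild-type level alone were the other choice fixed in advance. Before the data were examined, 29 gene lists were fixed, of which 28 had measured members. Of these, 5 lay outside the middle 95% of random lists matched on mean level and 5 outside that of lists matched on wild-type level, with 4 lists in common and 1.4 expected by chance under each. A further 9 lists were written later, before their values were looked at. List members were found by gene symbol, or by synonym where no annotated gene has the name as its symbol.

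Genes are named in the text by a rule fixed before the data were examined. It takes SPP1, the COMPASS subunits and the 5 genes with the highest wild-type level. It also takes the 8 lowest and 8 highest ratios among genes at or above the median wild-type level, and from each list the member with the highest wild-type level and those with the lowest and highest ratio. Because the left arm of chromosome IV filled most of the extreme places, the same rule was applied without that arm as well, a choice made after seeing the data.

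Alternatives covered a pseudocount of 10% of the wild-type median, floors at the 10th percentile and at the median of wild-type level, other summaries and thresholds, scaling of each library to its own total, 10 level classes in place of 5, matching on wild-type level alone, other distances from chromosome ends, and the exclusion of overlapping or subtelomeric genes. Added after seeing the data were the exclusion of chromosome IV left, subtraction of the 1st percentile of each library as background and counting genes with identical levels once. Matching on wild-type level and gene length together, and, for subtelomeric genes, both matchings other than that on mean level, were also added then. On simulated levels for 5038 genes, a set median log2 ratio of -2 was recovered as -2.01. Lists of 100 genes shifted by 1 and by -1 were recovered as 1.07 and -1.07. Of 40 unchanged lists, 1 lay outside the middle 95% of random lists matched on wild-type level. The simulated ratios did not depend on level, and the matching on mean level was not simulated, so its percentiles have no such check. On 200 simulated medians of 33 genes, 196 intervals held the true value. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.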

Results

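Histone H3 trimethylated on lysine 4 (H3K4me3), a mark of the 5′ part of transcribed genes, was measured by chromatin immunoprecipitation and sequencing in budding yeast of the BY4741 background. Wild type was set against a strain in which KanMX6, a drug resistance cassette, replaced SPP1. SPP1 encodes a PHD finger subunit of COMPASS, the complex that methylates H3K4 in this organism. The series holds 4 libraries, and the levels of 2 of them were used here, the H3K4me3 library of wild type and that of the spp1 deletion strain. Fission yeast cells had been added to both cultures, so that levels could be compared between strains as well as within them. A wild-type level was present for 5218 genes and a level in both strains for 5038. Each strain had 1 library, so no difference below has a replicate check or a p-value. Every interval is that of a summary over genes, taken as if they were independent, and says nothing about replicates. Read depth is not given in the sources used here.

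SPP1 itself was looked at first, as a check of the strain labels. The gene (YPL138C, chromosome XVI, 291366 to 292427) had an H3K4me3 level of 1.89 in the wild-type library and 0.0982 in the library of the deletion strain, 5.21% of wild type. That was the lowest ratio of all genes outside the left arm of chromosome IV, where spp1 levels scattered widely. By its level in the deletion strain alone, SPP1 ranked 4 from the lowest among all genes and 3 outside that arm. Why a replaced gene had a level above 0 was not tested. Of the other COMPASS genes, 6 were measured, and SWD2 was not analysed here. SET1, which encodes the methyltransferase, lay at 20.8% of its wild-type level (2.10 against 0.437), BRE2 at 20.2%, and SWD1 at 18.5%. SWD3 had a log2 ratio of -2.18, SHG1 lay at 31.7%, and SDC1 had the highest ratio of the group, with levels of 2.53 and 0.885. The median log2 ratio of the 6 genes was -2.22 (interval -2.44 to -1.51), a difference of -0.30 from the median of all genes. It lay at percentile 1.16 of 10000 random lists of 6 genes with like mean levels. Among lists matched on the wild-type level alone it lay at percentile 2.89, inside the middle 95%.

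The main question of the design was how much H3K4me3 remained genome-wide without Spp1. The median gene carried 26.3% of its wild-type level in the deletion strain, a log2 ratio of -1.93 (95% interval of the median over 5038 genes, -1.94 to -1.91). The middle 50% of genes lay between 20.8% and 34.1% of wild type, and the middle 90% between 15.5% and 52.7%. Levels had a median of 2.01 in wild type and 0.494 in the deletion strain, and the levels summed over genes came to 29.5% of the wild-type sum. Across genes, which are not independent replicates, the levels of the 2 libraries had a Spearman correlation of 0.76. The size of this difference rests on the authors' scaling between the libraries, which the series text ties to the spike-in. Dividing each library by its own total removes any factor common to a library, whatever its source. The median log2 ratio was then -0.17, and 38.4% of genes lay above wild type. Differences between groups of genes within the same pair of libraries do not move with such a factor.

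**Figure D1:**
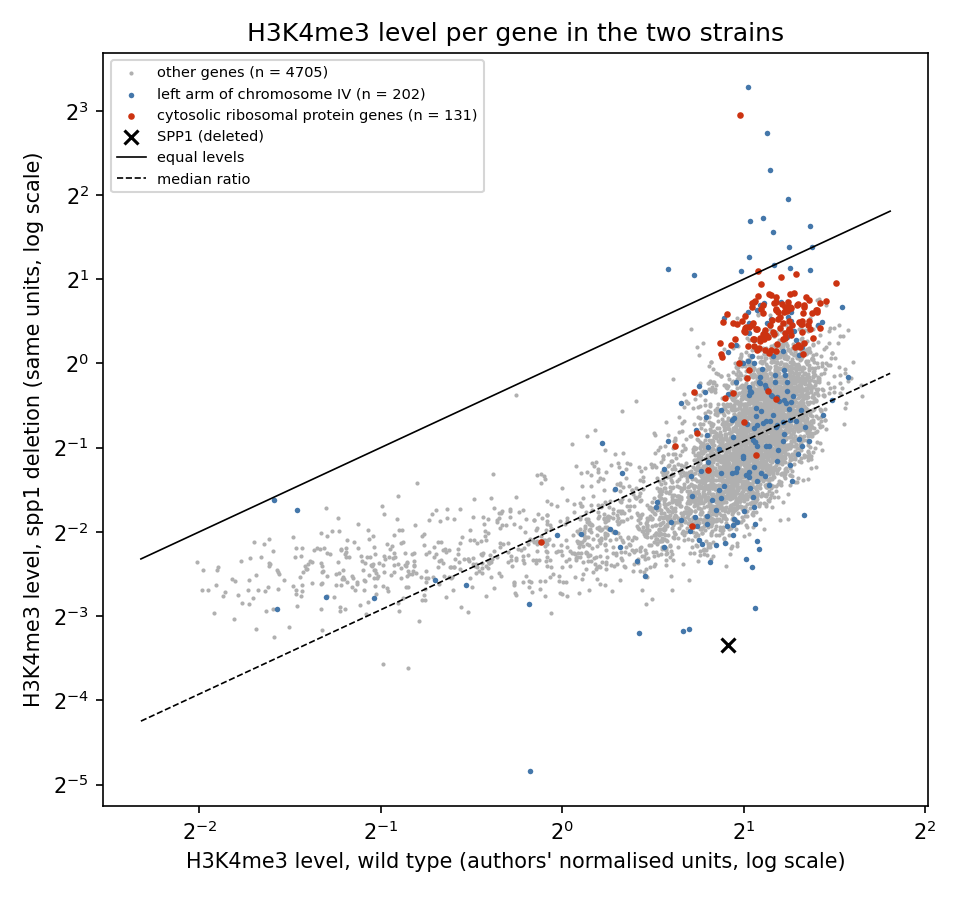
H3K4me3 level of each gene in the spp1 deletion library (vertical, log scale, the authors' normalised units) against its wild-type level (horizontal, log scale, same units); each point is 1 gene of 5038, the solid line marks equal levels and the dashed line the median ratio. Nearly all genes lie below the line of equal levels on the authors' normalised scale, SPP1 lies at 0.0982, and most of the 131 cytosolic ribosomal protein genes lie above the dashed line.

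Of the 5038 genes, 4727 (93.8%) carried less than 50% of their wild-type level and 2248 (44.6%) less than 25%. The share below 25% was 8.32% with a pseudocount, and with each library divided by its own total the shares were 3.31% and 0.0992%. The pseudocount, 0.201, lies above the 5th percentile of levels in the deletion strain, 0.192. Added to both levels, it draws every ratio towards equality, most where levels are low. Only 17 genes lay above wild type, and all 17 were on the left arm of chromosome IV, which held 212 of the genes. Among the 4826 genes elsewhere none did. The nearest was BCH2, at 91.7%, which was picked out after its value was seen. Among genes at or above the median wild-type level, chromosome IV left also held all 8 of the highest ratios and 6 of the 8 lowest. PTC1, a protein phosphatase gene (YDL006W, IV, 439909 to 440754), had a level of 2.03 in wild type and 9.71 in the deletion strain. IWR1, involved in nuclear import of RNA polymerase II, lay at 304.6% of wild type. TRM8 (tRNA methylation) lay at 222.1%, GET3 at 163.2%, the frataxin gene YFH1 at 157.4%, DLD2 at 153.5%, NOP6 at 131.6% and NRP1 at 119.7%. On the same arm LDB17 (IV, 192750 to 194225) lay at 6.36%, GRX6 at 9.08%, CYK3 at 9.91%, ASF2 at 10.2% and FAD1 at 11.4%, and UBP1 had levels of 2.11 and 0.232. The standard deviation of log2 ratios over the genes of this arm was 1.06, against 0.43 to 0.57 over the 29 other arms with both levels. The arm's median was -1.76, against -2.33 to -1.78 on the others. The 180 genes of chromosome IX had a wild-type level and no level in the deletion strain, and enter no comparison.

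**Figure D2:**
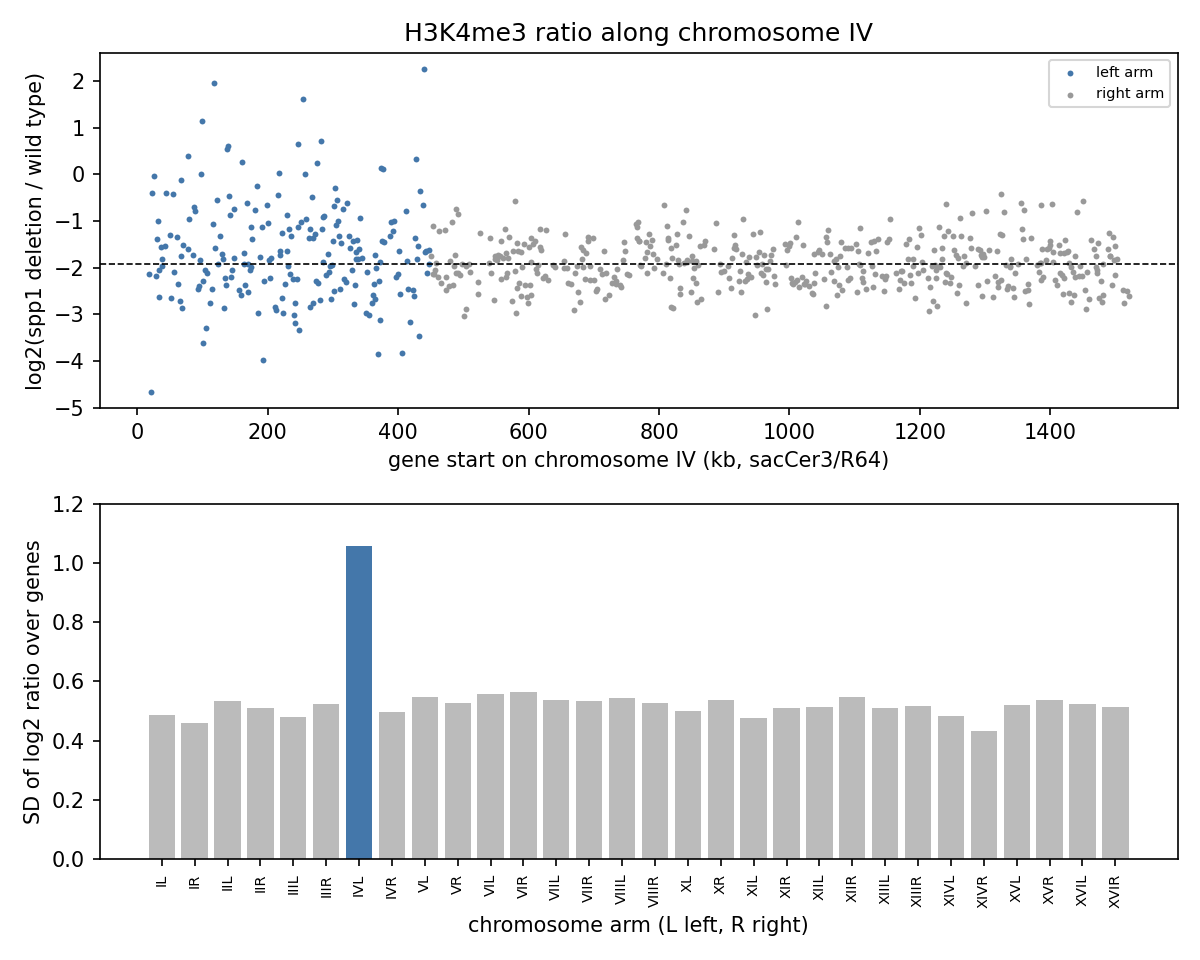
The upper panel plots the log2 ratio of the spp1 deletion strain to wild type for each gene against its start on chromosome IV (kb), with the dashed line at the median of all genes. The lower panel gives the standard deviation of the log2 ratio over the genes of each chromosome arm (bars from 0), which is 1.06 on chromosome IV left and at most 0.57 on any other arm shown.

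Among genes at or above the median wild-type level outside that arm, the 8 lowest ratios were spread over several chromosomes. PSK1, a PAS kinase gene (I, 120225 to 124295), went from 2.37 in wild type to 0.277 in the deletion strain, 11.7%. YHC3 (X, 324964 to 326190) lay at 11.8%, the transcription factor gene MSN1 (XV, 99809 to 100957) at 12.0%, ROG1 at 12.1% and YOL075C at 12.5%. RRG1 lay at 12.8%, the sterol reductase gene ERG27 at 13.0% and the reductase gene YPR1 at 13.2%. The 5 genes with the highest wild-type levels had ratios near the middle of all genes. UBP13, a ubiquitin protease gene (II, 93639 to 95882), carried 3.14 in wild type and 0.767 in the deletion strain. SLY1 (vesicle fusion) lay at 26.7% of wild type, IOC2 (a chromatin remodeller subunit) at 33.2%, and UTP14 at 29.5%. CWC2, on chromosome IV left, had levels of 2.98 and 0.895.

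Genes with little H3K4me3 in wild type were compared with genes with much of it. Sorted into 5 equal classes by wild-type level, the genes had median log2 ratios of -2.01, -2.17, -1.96, -1.82 and -1.70 from the lowest to the highest class. The top class lay 0.30 above the bottom one (interval 0.25 to 0.37), and the class next to the lowest lay below both. Sorted by the mean log2 level of both libraries, the medians were -2.16, -2.33, -2.07, -1.76 and -1.33. That ordering contains the deletion strain's own level, which can widen the contrast. Wild-type level is the denominator of the ratio, so noise in it can lower the contrast when genes are sorted by it. Neither ordering is free of bias. The difference between top and bottom was not stable: it was -0.041 with 10 classes in place of 5 and -0.030 with a pseudocount. Every other setting tried gave a positive difference. These ranged from 0.25 with the floor at the median to 0.97 after background subtraction, a setting chosen after seeing the data. Across genes the Spearman correlation of the log2 ratio was 0.22 with wild-type level and -0.11 with gene length.

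**Figure D3:**
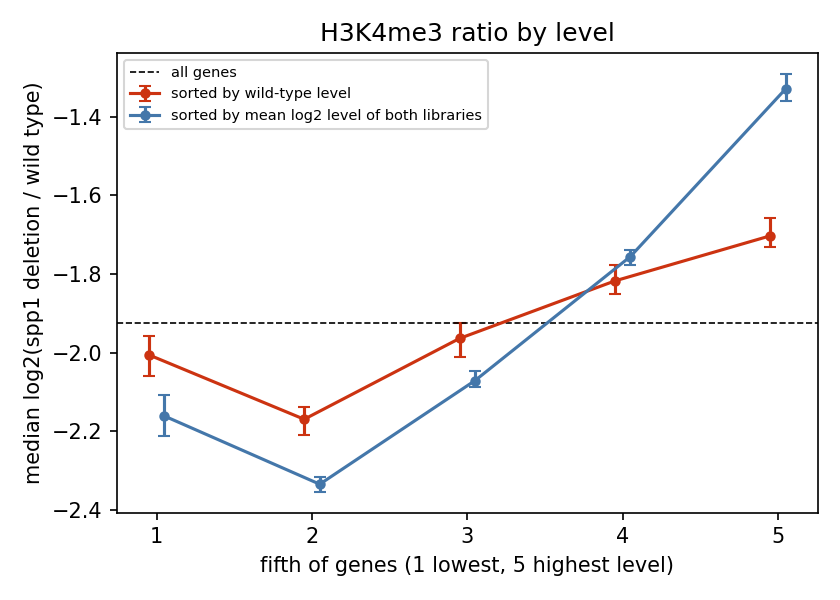
Median log2 ratio of the spp1 deletion strain to wild type (vertical) in each of 5 equal classes of genes (horizontal, lowest to highest level), sorted by wild-type level or by the mean log2 level of both libraries. Bars are 95% intervals of the median over about 1008 genes, and the dashed line is the median of all genes, -1.93.

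The genes for cytosolic ribosomal proteins had the highest median ratio of all the lists fixed in advance. Of 137 annotated, 131 were measured, and their median level in the deletion strain was 60.0% of wild type, a log2 ratio of -0.74 (interval -0.79 to -0.65), which is 1.19 above that of all genes. Of these genes, 127 lay above the all-gene median and 108 at or above 50% of wild type. None of 10000 random lists of the same size reached their median, whether matched on mean level (random median -0.97) or on wild-type level (-1.83). The 76 genes of the large subunit (60.7%) and the 55 of the small subunit (59.6%) were alike. Outside chromosome IV left, among genes at or above the median wild-type level, the 8 highest ratios all belonged to ribosomal protein genes. RPL34A (V, 269423 to 270185) had levels of 2.14 and 1.92, or 89.5%, and RPS10A (XV, 867098 to 867852) lay at 88.1%, RPL6A at 85.3%, RPL27A at 82.3% and RPL22A at 80.4%. RPL17A lay at 80.0%, RPS25A at 79.7% and RPL8B at 79.5%. Of the 100 highest ratios among all 4826 genes outside that arm, 59 were those of ribosomal protein genes. The lowest member outside that arm was RPS14B, at 22.5%. On chromosome IV left, RPS16B, the member with the highest wild-type level, lay at 68.1%, while RPL35A lay at 390.8% and RPL41B at 15.9%. Their place relative to wild type rests on the authors' scaling between the libraries. With each library divided by its own total, 127 of the 131 lay above wild type and 4 below, with a median log2 ratio of 1.02 and RPL34A at 1.60.

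The proteasome list had 33 measured genes at a median of 44.4% of wild type (log2 -1.17), and 31 of them lay above the all-gene median. RPN11, a lid subunit gene, lay at 69.0% and PRE4, with the highest wild-type level of the list, at 42.8%. The lowest members were RPN4 (18.3%, on chromosome IV left), the transcription factor gene of the proteasome regulon, and outside that arm RPN14 (23.4%), which encodes an assembly factor. The list's median was above 97.6% of random lists matched on mean level and above all those matched on wild-type level. Without chromosome IV left it was above 90.01% of the former and still above all of the latter. The 67 ribosome biogenesis genes had a median of 37.0% (log2 -1.44), with 57 above the all-gene median. RLP7 lay at 74.3%, NOP58 at 38.9%, RIX1 at 21.5%, and NOP1, on chromosome IV left, at 125.1%. Their median was above all random lists matched on wild-type level, with or without gene length. It was at percentile 50.1 of those matched on mean level, a matching that contains the deletion strain's own level. RNA polymerase I and III subunits (19 genes, median 31.5%, percentile 9.98 of lists matched on mean level and 79.1 of those matched on wild-type level) ranged from RPC34 at 20.2% to RPC53, on chromosome IV left, at 83.6%. RPC31, with the list's highest wild-type level, lay at 29.8%. The 62 mitochondrial ribosomal protein genes lay at 30.6%, at percentile 54.0 matched on mean level and 96.9 matched on wild-type level (97.51 without chromosome IV left, just outside the middle 95%), with MRPL40 at 28.5%, MRPL44 at 17.6%, MRPL28 at 63.3% and MRPL11, on chromosome IV left, at 100.5%.

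The 19 glycolysis and fermentation genes had a median of 33.5% of wild type (log2 -1.58), above 99.99% of random lists matched on mean level. TDH3, a glyceraldehyde phosphate dehydrogenase gene, lay at 55.5%, HXK2 at 23.5% and GLK1, which overlaps another annotated gene, at 20.98%. Wild-type levels in this list were low, with a median of 1.65, and among genes at or above the median wild-type level the members left lay 0.27 below all genes (log2 difference -0.27). That floor was 2.01 and the list's highest wild-type level was 2.05 (HXK2), so only members between these levels gave this value. The 9 core histone and histone variant genes had a median of 30.6% (percentile 99.94), with HTA1 at 40.5%, HTZ1 at 31.3% and HTB2 at 23.2%. Matched on wild-type level and gene length together, the histone list was at percentile 85.5. Several histone genes have near-identical copies, and how shared reads were assigned is not given in the sources used here.

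The other metabolic lists had percentiles inside the middle 95% of random lists under both matchings (those on mean level are given). The tricarboxylic acid cycle and respiration genes (43, median 26.0%, percentile 74.4) ranged from LSC2 at 11.4% to ATP17 at 45.9%, with ATP14 at 39.8%. Amino acid biosynthesis genes under Gcn4 (43, 24.3%, percentile 4.16) ranged from ORT1 at 12.9% to ILV5 at 43.9%, and ARO1 lay at 18.1%. Ergosterol genes (24, 23.6%, percentile 42.7) ranged from ERG27 to ERG9 at 33.8%, with ERG2 at 27.9%. Phosphate regulon genes (15, 29.9%, percentile 90.6) ranged from PHO8 at 17.0% to the polyphosphate synthase gene VTC4 at 46.1%. Several lists are little transcribed in glucose medium, and their wild-type levels were low. The 6 galactose genes had a median level of 0.549 in wild type and lay at 38.6% (percentile 82.8), with GAL80 at 27.4%, GAL4 at 26.4% and GAL2 at 52.2%. Their difference of 0.55 from all genes was 0.083 among genes at or above the 10th percentile of wild-type level, where GAL80 alone is left. It was 0.078 after background subtraction, which drops GAL2. The 12 genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation had a wild-type median of 0.516 and lay at 35.9% (percentile 75.1), from ICL1 at 15.9% to SFC1 at 78.4%, with MDH2 at 25.8%. Their difference from all genes, 0.44 on the log2 scale, turned to -0.67 among genes at or above the 10th percentile of wild-type level and to -0.33 after background subtraction. Of the hexose transporter genes, 5 were measured (29.0%, percentile 86.1), with HXT1 at 19.1% and HXT7 at 51.5%, and their difference of 0.14 turned to -0.29 and -0.22 in the same order. That floor, 1.09, lies above the wild-type medians of the gluconeogenesis and hexose transporter lists (0.516 and 0.945). The values of -0.67 and -0.29 therefore rest only on the members left above it.

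The lists of factors that act before or after COMPASS lay inside the middle 95% of random lists under both matchings. Genes of the Paf1 complex and of H2B ubiquitination, which act before H3K4 methylation, had a median of 34.3% (10 genes, percentile 38.3), with PAF1 at 24.5% and LEO1 at 49.3%. Readers and erasers of H3K4 methylation had a median of 25.1% (8 genes, percentile 26.4). Among them the H3K4 demethylase gene JHD2 lay at 15.8%, YNG1 at 25.8% and YNG2 at 41.7%. The same held for the stress response genes (36, 24.3%, percentile 79.8, or 23.1 matched on wild-type level), from GAD1 at 12.9% to HSP12 at 59.9%, with SSA3 at 19.2%. The wild-type level of HSP12, 0.258, lay below the 0.362 taken as background, as did those of SFC1 and GAL2, so these ratios compare very low levels. The stress list's difference of -0.12 from all genes was -0.42 after background subtraction, -0.60 at or above the median wild-type level and 0.06 with a pseudocount. The floor at the median, 2.01, lies above the list's own wild-type median of 1.55, so the -0.60 rests on part of the list. Cell cycle genes (33, 26.1%, percentile 59.9) ranged from ASE1 at 15.2% to PCL9, on chromosome IV left, at 145.4%, and CDH1 lay at 22.3%. Splicing genes (34, 29.8%, percentile 76.1) ranged from SMX2 at 15.4% to PRP8 at 47.9%. The vesicle traffic genes, chosen for comparison, had a median of 30.4% (33, percentile 43.4), with YPT32 at 15.2%, SEC17 at 27.8% and ARF2, on chromosome IV left, at 73.5%.

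Genes under cell type control were few in the table. The 4 measured a-specific genes, active in this MATa strain, had a median of 29.2% (percentile 91.8), with MFA1 at 26.9%, AGA2 at 15.2% and STE2 at 34.2%. Their difference from all genes, 0.15, turned to -0.35 with the floor at the 10th percentile of wild-type level, where MFA1 and AGA2 are left. With the floor at the median it was -0.11, where MFA1 alone is left. Of the alpha-specific genes 2 were measured, SAG1 at 13.7% and STE3 at 41.6% (percentile 20.2, or 4.60 matched on wild-type level). Their difference from all genes, -0.14, was -0.91 and -1.08 with these floors, where SAG1 alone is left. Pheromone response and haploid-specific genes lay at 24.7% (13, percentile 47.7), from SST2 at 15.7% to STE20 at 46.9%, and STE7, on chromosome IV left, at 24.2%. Meiosis and sporulation genes lay at 26.6% (13, percentile 44.7), from IME1 at 15.8% to SPR1 at 50.04%, with REC107 at 18.6%. Of the loci altered as auxotrophic markers in BY4741 1 was measured, HIS3, at 31.6% (percentile 78.8), and no mitochondrially encoded gene had a level.

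**Figure D4:**
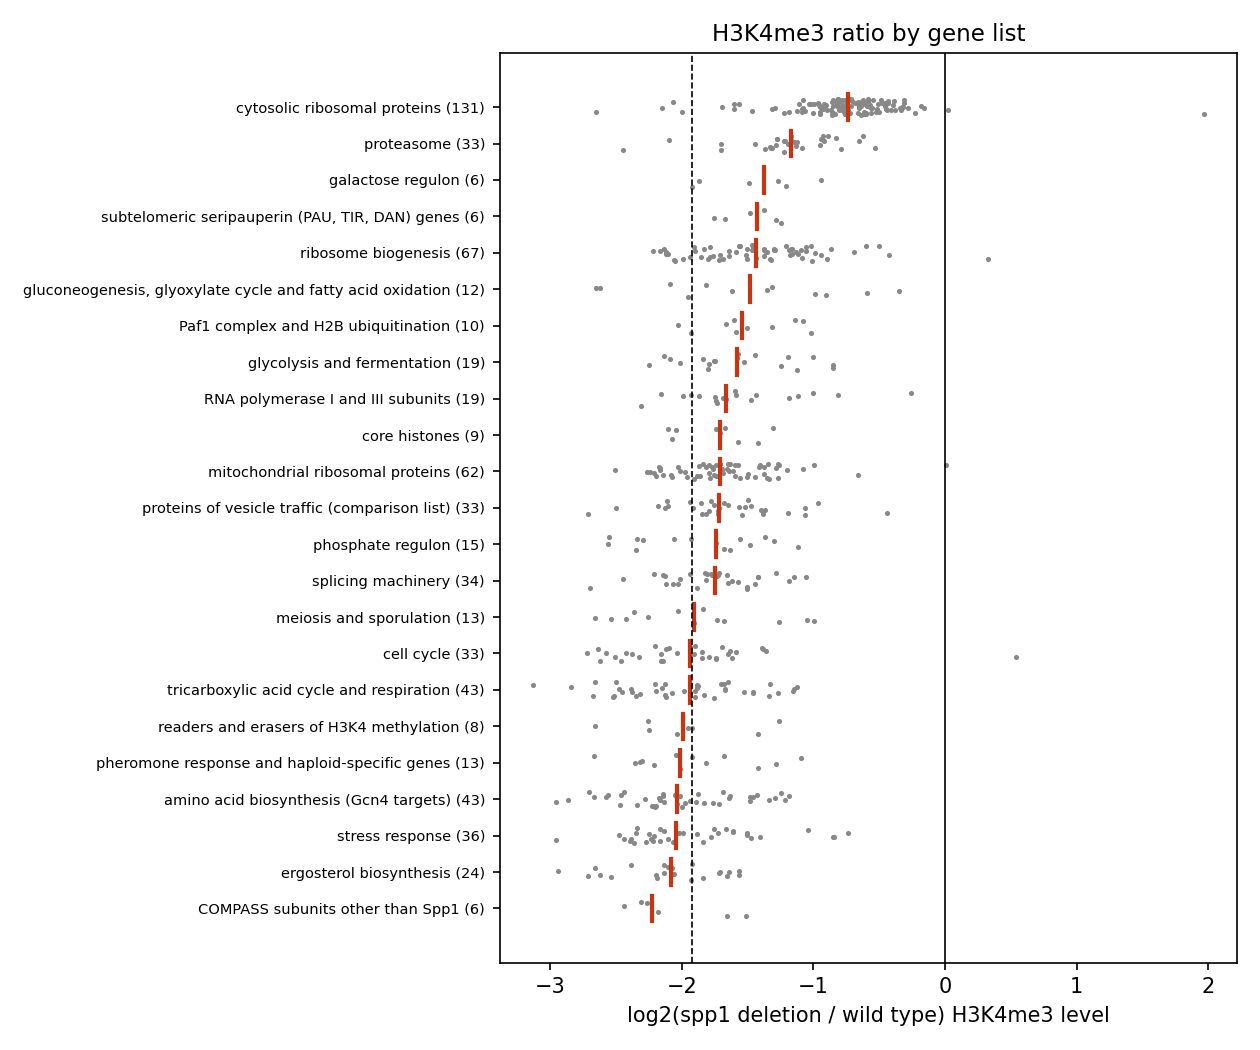
Log2 ratio of the spp1 deletion strain to wild type (horizontal) for each measured gene (grey points) of the lists fixed in advance with at least 6 measured members, number of genes in brackets. Red bars are list medians, the dashed line is the median of all genes (-1.93) and the solid line marks equal levels on the authors' normalised scale. The cytosolic ribosomal protein list has the highest median, -0.74.

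Genes near chromosome ends were compared with the rest, since COMPASS mutants are known for defects there. The 77 genes within 20 kb of the outermost annotated gene end of a chromosome lay at 23.7% of wild type (log2 -2.08, interval -2.35 to -1.90), against 26.3% (log2 -1.92) for the other 4861 placed genes. The difference of -0.15 had an interval over genes of -0.36 to -0.004. It was -0.34 among genes at or above the 10th percentile of wild-type level, -0.65 after background subtraction and -0.022 with a pseudocount. The subtelomeric genes were at percentile 12.7 of random lists matched on mean level. Matched on wild-type level they were at percentile 1.66, outside the middle 95%, and with gene length added at 4.24, inside it. The last 2 matchings were chosen after seeing the data. Their wild-type median, 1.48, was below that of the rest, 2.02. Of the families listed as subtelomeric, 6 PAU, TIR and DAN genes lay at 37.1% (percentile 38.6), with TIR4 at 31.4%, TIR1 at 29.6% and PAU23 at 42.1%. Their difference from all genes, 0.49, was still 0.49 without genes within 20 kb of an end, so it does not describe genes that near an end. It was 0.75 with a pseudocount and 0.03 after background subtraction. Of the COS genes 1 was measured, COS10, at 22.9% (percentile 70.9).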

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

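Leaving out chromosome IV left, subtracting a background of the 1st percentile of each library and counting genes with identical levels once were chosen after seeing the data. So were matching on gene length and matching subtelomeric genes on wild-type level. The rest was planned. No paired analysis was possible because each strain had 1 H3K4me3 library. The planned background from mitochondrially encoded genes and the planned ratio to input were not run, since no such gene and no input level was in the columns used, and SPP1 has no value after background subtraction because its level in the deletion strain lies below the background. For the 23 lists with an interval over genes, 160 of 180 differences from all genes stayed inside it; 11, in 6 lists, took the other sign. The 5 lists with too few genes for an interval gave 36 differences, of which 6, in 4 lists, took the other sign. Floors and background subtraction also changed which members a list held. Where a value below differs and no cause is stated, the cause was not tested. Depth, which is unknown, limits the lowest levels most.

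The genome-wide log2 ratio of -1.93 was -1.57 with the pseudocount, -1.95 and -1.78 with floors at the 10th percentile and the median of wild-type level, -1.76 from summed levels, -1.90 as a trimmed mean and -2.17 after background subtraction. With each library scaled to its own total it was -0.17, since that removes any factor common to a library, whatever its source. Under that scaling 3.31% of genes lay below 50%, 0.0992% below 25% and 38.4% above wild type, and SPP1 had a log2 ratio of -2.50. The COMPASS genes and those named for an extreme level or ratio were looked at singly. Of these, the sign reversed for SHG1 (0.10), SDC1 (0.25), IOC2 (0.17) and CWC2 (0.024). It also reversed for RPL34A (1.60), RPS10A (1.58), RPL6A (1.53), RPL27A (1.48), RPL22A (1.44), RPL17A (1.44), RPS25A (1.43) and RPL8B (1.43). Genes named only as list members were not looked at singly. Any gene below wild type but above 29.5% of it, the ratio of summed levels, turns above wild type under this scaling. With the pseudocount SPP1 was at -2.80 and 8.32% of genes lay below 25%. The pseudocount, 0.201, was large beside the median level in the deletion strain, 0.494, and draws ratios towards equality by construction. The share above wild type, 0.337%, was 0.514% at or above the median wild-type level, 0.139% with a threshold of 1.5, 1.03% after background subtraction and 0 without chromosome IV left.

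The top minus the bottom of 5 classes by wild-type level, 0.30, reversed to -0.030 with the pseudocount and to -0.041 with 10 classes. It was 0.57 with the lower floor, 0.83 sorted by the mean of both libraries and 0.97 after background subtraction. The subtelomeric difference of -0.15 was -0.65 after background subtraction, and its percentile of 12.7 was 1.66 matched on wild-type level, outside the middle 95%. The ribosomal protein list, 1.19 above all genes, was 0.90 above with the pseudocount, 1.04 above among genes at or above the median wild-type level and 1.51 above after background subtraction. In the same order the ribosome biogenesis list was 0.35, 0.33 and 0.70 above, and the proteasome list 0.52, 0.61 and 1.01 above. The glycolysis list reversed to -0.27 among genes at or above the median wild-type level, where the stress response list went from -0.12 to -0.60 and the alpha-specific list from -0.14 to -1.08. That floor left only part of each of these lists, and of the alpha-specific list SAG1 alone. The COMPASS list was at percentile 2.89 matched on wild-type level and 3 with length added. Ribosome biogenesis was at percentile 100 under both, and the proteasome list at 90.01 without chromosome IV left.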

Other observations

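The tests of misplaced values, of copy number and of a divided-by library on chromosome IV left, and that of the arm's weight in the ribosomal protein list, were set out after the patterns were seen, and the gene lists of the next paragraph were written after the fixed ones.

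Of the lists written later, 4 had higher ratios than random lists matched on wild-type level. Translation initiation and elongation factor genes lay at a median of 45.7% of wild type (25 genes, 23 of them above the all-gene median), with TIF35 at 74.6%, TIF34 at 59.2% and TEF4, which overlaps another annotated gene, at 19.7%. Cytosolic aminoacyl-tRNA synthetase genes lay at 41.0% (17 genes, from HTS1 at 23.3% to SES1 at 59.5%, with GLN4 at 34.95%). The genes of CCT, the ring chaperonin that folds actin and tubulin, lay at 48.4% (7 genes, from CCT3 at 34.0% to CCT8 at 56.2%, with CCT7 at 36.7%). Genes of the vacuolar proton pump lay at 38.1%, all 17 above the all-gene median, from VMA9 at 27.3% to VMA2 at 63.2%, with VMA16 at 42.3%. Matched on wild-type level, these 4 lists were above 99.8% or more of random lists. Matched on mean level they were at percentiles 96.3, 84.2, 96.1 and 98.0, and without chromosome IV left the CCT list was at 33.4, against 98.6 matched on wild-type level.

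Autophagy genes stood at the other end. Their median was 18.4% of wild type (33 genes, log2 -2.44, interval -2.62 to -2.08), at percentile 0.285 of random lists matched on mean level and below all of those matched on wild-type level. ATG18 lay at 22.4%, and on chromosome IV left ATG9 lay at 12.7% and ATG20 at 100.5%. Nuclear pore genes lay at 29.3% (25 genes), with GLE2 at 31.4%, NUP120 at 18.6% and GLE1, on chromosome IV left, at 58.2%. That list was at percentile 46.3 matched on wild-type level and 76.5 with gene length added; its percentile of 0.17 came from matching on mean level, which contains the deletion strain's own level. The amino acid permease (14 genes, 29.8%, percentile 96.5), mitochondrial import (22, 31.4%, 91.3) and vacuolar protein sorting genes (41, 25.7%, 36.6) were inside the middle 95%. Their lowest and highest members were MUP1 (14.7%) and LYP1 (35.9%), TIM12 (20.1%) and TIM22 (91.5%, on chromosome IV left), and VPS62 (16.3%) and VPS21 (48.1%), and VPS16, with the highest wild-type level of its list, lay at 26.2%.

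The high ratios of cytosolic ribosomal protein genes were weighed against technical sources. Without chromosome IV left the list lay 1.21 above all genes, and random lists matched on wild-type level (median -1.83) or on wild-type level and gene length (median -1.74) never reached its median of -0.74. The 19 members without a duplicated copy, which share no reads with one, had a median of -0.72, above all matched random lists. These values argue against the scatter of that arm, the wild-type level, short genes and shared reads as the whole cause. How levels were averaged over each gene stays open, and no biological explanation was tested.

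If a shared promoter region passed the high ratio on, genes divergently transcribed from a ribosomal protein gene could be expected to share it. The 57 measured neighbours of this kind had a median log2 ratio of -1.85, or 27.7% of wild type, at percentile 71.9 of random lists matched on wild-type level (middle 95%, -2.05 to -1.74). As a set these neighbours thus did not share the high ratio. No limit was set on the distance between the genes of a pair, so some pairs may share no promoter region and dilute the median.

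The scatter of spp1 levels on chromosome IV left was weighed against technical sources. Values beside the wrong genes are argued against by a Spearman correlation with wild type of 0.58 along the arm, against at most 0.16 over 40 shifted orders. A gain or loss of the whole arm would multiply all its genes alike. Alone it would not give the standard deviation of 1.06 (bootstrap interval 0.94 to 1.18). That value is the pattern itself and cannot tell whether such a change was present besides. The arm's median of -1.76 lay above the highest of the other arms, -1.78. Too few reads on the arm, either in the precipitated spp1 library or in a library its levels were divided by, cannot be told apart from each other or excluded. The extra variance of the 56 arm genes with low wild-type levels was 1.06 times that of the 77 with high levels, with a bootstrap interval of 0.36 to 2.42, and the skewness of residuals, 0.62 (0.16 to 1.03), has an interval that holds the 0.31 of other arms. No biological explanation was tested, and ratios of single genes on this arm are less certain than elsewhere.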
